A study of Homo sapiens with 9 samples.

How the data were processed

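The series holds 9 poly-A-selected RNA libraries, sequenced from both ends with 50 bp reads, from U87 human glioblastoma cells that carried a lentiviral vector. The labels put 3 replicate cultures in each of 3 groups: control vector, Myt1 vector and Myt1l vector. They give no batch, date or pairing. The submitters' processing notes name FastQC, STAR, featureCounts and DESeq2 and the genome build GRCh38. The sources used here do not give versions, the annotation release, the counting strand or any filter. The unit of the deposited table is signal: per the values, it holds gene reads divided by 1 size factor per library, for 58830 gene symbols and 9 libraries.

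Whole reads were recovered by multiplying each column by its size factor. At a tolerance of 0.001 reads, 100% of values were whole, and the implied factors matched DESeq2 median-of-ratios factors computed from the recovered reads within 2.7e-12. The recovered reads totalled 15598124 to 29928017 per library. A count of 0 allows up to 3 reads per library, and this limit covers counting error only. Of the 58830 symbols, 22567 were at 0 in every library and 28 had been turned into dates by a spreadsheet, so those genes could not be named. Positions, gene types, GC content, transcript length and exon overlap came from GENCODE 29, to which 37968 symbols were matched, 767 of them through an older symbol. The remaining 20862 symbols kept their values and had no position.

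The main test was limma on log2(value + 1) of the deposited values, for the 17074 genes with at least 10 normalised reads in at least 3 libraries. A model with 1 mean per group over all 9 libraries was fitted, followed by empirical Bayes moderation with a trend on the mean level and robust settings. All tests were two-sided, and Benjamini-Hochberg adjusted p under 0.05 counted as called. The plan named edgeR on deposited counts as the main test, and because the deposited values are not counts, edgeR on the recovered reads became an alternative. The comparisons were Myt1 vs control, Myt1l vs control and Myt1l vs Myt1.

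Gene lists were tested with camera in the same limma model, with a preset inter-gene correlation of 0.01, for lists with at least 5 tested members, adjusted over lists. Each was also tested with a correlation estimated from the data and with fry. Counts of members were taken over all genes and adjusted over the list alone. The lists were the Notch pathway, BMP and TGF-beta immediate targets, Wnt pathway targets, YAP/TAZ targets, neuronal cytoskeleton and synapse, proneural and neuronal transcription factors, ion channels and neurotransmitter receptors, neural progenitor and astroglial genes, and the oligodendrocyte lineage. They went on with mesenchymal glioblastoma genes, inflammatory cytokines and NF-kappaB targets, interferon-stimulated genes, antigen presentation, DNA replication, mitosis, p53 targets, the unfolded protein and integrated stress response, heat shock response and immediate early genes. Collagens and extracellular matrix, integrins and cadherins, matrix proteases, epithelial-mesenchymal transition regulators, axon guidance, growth factors and receptor tyrosine kinases, cholesterol synthesis, hypoxia and glycolysis, the respiratory chain, mitochondrially encoded mRNAs, ribosomal proteins and replication-dependent histones followed. The last were smooth muscle, skeletal muscle, melanocyte and neural crest, macrophage and microglia, endothelial and epithelial genes, MYT1-associated chromatin regulators, REST target neuronal genes and housekeeping reference genes.

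The groups, comparisons, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule named MYT1, MYT1L and ST18. For each comparison with control it took the 10 genes with the largest rise and the 10 with the largest fall among called genes with groups that did not overlap and a mean of at least 5 CPM in the higher group. It took 5 and 5 between the vector groups and 5 and 5 of the genes shared by both comparisons with control. From each list that was called, or had at least 2 called members, it took up to 4 members with the smallest adjusted p. Some of the 291 genes it gave are named in the text. Exons of another gene covered at least 10% of exon bases in 31 of them, and these were not taken as examples in the report.

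The covariance and correlations of log2 fold changes between both comparisons with control were set beside those of 100 simulated draws. Each draw simulated every library from the control means without change, so both comparisons shared 3 simulated controls. Alternatives covered the normalization, the filter, the test, the libraries in the model, a replicate block, the threshold, the pseudocount, the variance trend, removal of the trend with GC content and length (14826 genes) and leaving out each library in turn. The test of limma was checked on simulated data with 200 changed genes. These were drawn from genes above a minimum level in the controls, so the rates do not cover genes with few reads there. It called 64.2% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold for Myt1 vs control, and 2.34% of its calls were unchanged genes. Only 200 genes were changed in each simulated vector group, whereas the real comparisons with control called 41.8% and 47.7% of genes. The simulation also held no GC trend, so these rates may not carry over to the real data. A planned test for the binding motif of this factor family near promoters was not run, because no genome sequence was at hand. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.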

Results

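RNA was measured in U87 cells, a human glioblastoma line grown in culture, that carried an integrated lentiviral vector. The 9 poly-A-selected libraries fell into 3 groups of 3 replicate cultures each: cells with an empty vector (control), cells with a vector for Myt1 and cells with a vector for Myt1l. Myt1 and Myt1l are zinc finger transcription factors best known from developing neurons. The question was which genes each factor turns up or down in glioblastoma cells, and whether both act on the same genes. The deposited values were gene reads divided by a size factor per library, and the whole reads recovered from them totalled 22111641, 24874798 and 29928017 in the control libraries. They totalled 16165273, 29853836 and 15598124 in the libraries labelled Myt1 and 20116637, 23854961 and 20687219 in those labelled Myt1l. Levels below are size-factor-normalised reads, as mean ± SD with n = 3. Log2 fold changes are of value + 1, with their standard error, so that small counts understate them. Positions are on GRCh38, and adjusted p values come from limma over 17074 genes.

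The genes named in the labels came first, as a check of the labels. MYT1 (chromosome 20, 64102394 to 64242253) was listed at 0 in all 9 libraries, as were all 13 mitochondrially encoded mRNAs, so nothing was read from that 0. MYT1L (chromosome 2, 1789113 to 2331664) stood at 417, 778 and 478 normalised reads in the controls, at 97.1, 112 and 95.8 in the libraries labelled Myt1 and at 199, 236 and 245 in those labelled Myt1l. Its log2 fold change against control was -2.39 ± 0.20 (adjusted p = 7.3e-06) with the Myt1 label and -1.25 ± 0.20 (adjusted p = 6.3e-04) with the Myt1l label. The libraries labelled Myt1l held more MYT1L than those labelled Myt1 (1.15 ± 0.20, adjusted p = 0.003). That call was lost with limma-voom (adjusted p = 0.076) and with a test for at least 1.5-fold (0.480), in a range of 1.3e-06 to 0.480 over all alternatives. Exons of other genes covered 5.0% of MYT1L's exon bases. ST18, the remaining member of this zinc finger family, fell from 162 ± 13.3 to 88.8 ± 6.79 (-0.86 ± 0.12, adjusted p = 3.7e-05) and 76.8 ± 5.10 (-1.07 ± 0.12, adjusted p = 4.2e-06). MYT1L therefore went against the labels, and the labels do not say from which species or in which part the vector sequences came. Every direction below rests on the group labels, and the groups are named as the libraries labelled Myt1 and Myt1l.

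**Figure D1:**
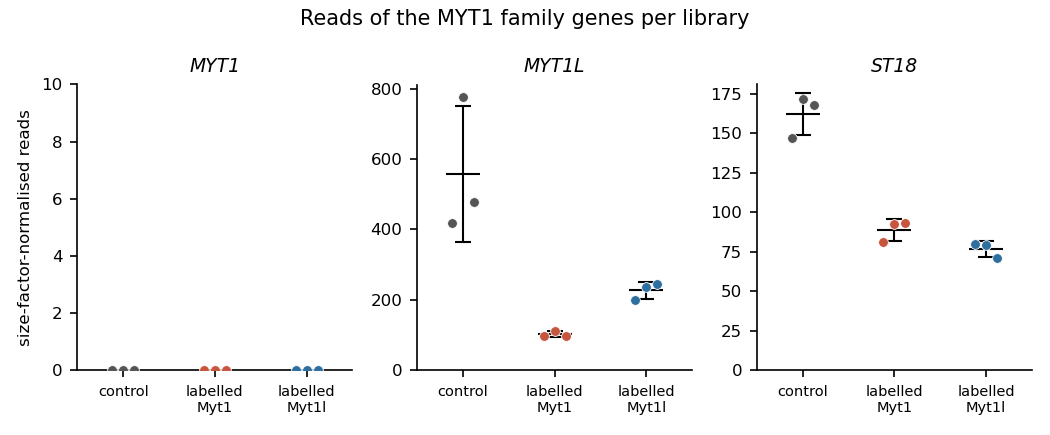
Normalised reads of MYT1, MYT1L and ST18 (linear axis) in each library, with points for libraries and bars for the mean ± SD of the 3 libraries of a group. MYT1L ran from 417 to 778 in the controls, from 95.8 to 112 in the libraries labelled Myt1 and from 199 to 245 in those labelled Myt1l.

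Libraries of each group resembled each other more than libraries of another group. Across genes, which are not independent replicates, log2 values correlated at r = 0.9874 to 0.9917 within groups and at 0.9642 to 0.9856 between them. The first principal component held 47.9% of the variance and the second 19.2%. Replicates differed by more than counting error, with a chi-square per degree of freedom of 2.46 to 13.24. Replicate 3 of the libraries labelled Myt1l stood furthest from its group, at 10.81 and 13.24. GC content differed between libraries too. In the controls, genes in the fifth with the highest GC content lay -0.35 to -0.25 (log2) from those in the fifth with the lowest. The same value was 0.04 to 0.12 in the libraries labelled Myt1 and 0.08, 0.11 and 0.44 in those labelled Myt1l, the last in replicate 3. Because the counting strand is not stated, reads of overlapping genes are uncertain. Exons of other genes covered 5.5% to 9.9% of exon bases in NCAM1, PMEPA1, DNAJB1, KCNA1, THBS1, SCN9A, RPL4, SLC7A11, HMG20B, DEPTOR, DKK1 and SCN3A.

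In the libraries labelled Myt1, genes of neurons rose against control and genes of cell division fell. The neuronal list kept its call with an estimated correlation (adjusted p = 0.029), while the mitosis list lost it (adjusted p = 0.083). GAP43, a protein of growing axon tips, rose from 155 ± 12.6 to 1639 ± 105 normalised reads (3.39 ± 0.08, adjusted p = 5.2e-13). SYP, the synaptic vesicle protein synaptophysin, rose from 52.7 ± 5.30 to 479.8 ± 32.5 (3.17 ± 0.12, adjusted p = 2.3e-11). The connexin gene GJA1, which encodes a gap junction protein of astrocytes, fell from 6280 ± 24.0 to 663 ± 72.1, or 9.50-fold (-3.25 ± 0.07, adjusted p = 2.8e-13). Of 17074 genes tested, 3660 were higher and 3482 lower than control, and 776 and 517 of these differed by at least 2-fold. The larger side turned with TMM factors from all genes, to 3282 higher and 3878 lower, and with the GC and length trend removed, to 3196 and 4099. EdgeR, with TMM factors from the genes left by its filter, did not turn it, with 3940 higher and 3289 lower.

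Among the named genes, the steepest rise was in NTS (chromosome 12, 85874295 to 85882992), the precursor of the neuropeptide neurotensin. It went from 4.85 ± 1.17 to 2470 ± 252 (8.74 ± 0.15, adjusted p = 4.8e-14). PTGS1, which encodes the cyclooxygenase of constitutive prostaglandin synthesis, rose by 6.70 ± 0.21 (adjusted p = 2.1e-11), and ARHGAP36 by 6.97 ± 0.29 (adjusted p = 8.8e-11). S100A9, a calcium-binding protein of myeloid cells, reached 314 ± 45.5 from 3.61 ± 2.23. SOST, a secreted Wnt inhibitor, rose by 6.03 ± 0.22, and RCAN2, a regulator of calcineurin, by 6.08 ± 0.15. DRAXIN, an axon guidance protein, rose by 5.34 ± 0.18, and NOS1, the neuronal nitric oxide synthase, by 4.53 ± 0.13. NFATC4, a calcineurin-dependent transcription factor, fell from 124 ± 3.08 to 2.54 ± 0.342 (-5.15 ± 0.29, adjusted p = 3.2e-09). IFI44L, an interferon-stimulated gene, fell from 556 ± 24.6 to 34.1 ± 3.53. In each of these genes all 3 libraries of one group lay above all 3 of the other. The rule for the largest changes asked for this, so it is no separate result.

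Neuronal cytoskeleton and synapse genes rose together. Of 34 tested members, 26 rose, 2 fell and 6 did not pass (27 and 3 adjusted over the list alone), at adjusted p = 9.4e-12 for the list and adjusted p = 0.029 with an estimated correlation. This was the list call that held with an estimated correlation. Beside GAP43 and SYP, its risers included DCLK1, a microtubule-binding kinase of migrating neurons (2.43 ± 0.08, adjusted p = 5.8e-12), and NCAM1, the neural cell adhesion molecule (1.61 ± 0.06). Neuronal genes known to be silenced by the repressor REST moved the same way. Of 21 tested, 18 rose, 1 fell and 2 did not pass (18 and 1 adjusted over the list alone), at adjusted p = 2.3e-08 for the list and adjusted p = 0.105 with an estimated correlation. VGF, a secreted neuropeptide precursor, went from 1564 ± 125 to 7539 ± 445, and BEX1 rose by 1.26 ± 0.06 (adjusted p = 8.0e-10). REST itself fell from 1136 ± 44.2 to 705 ± 47.9 (-0.69 ± 0.07, adjusted p = 1.9e-06), as did HMG20B, a partner of the REST corepressor complex (-0.83 ± 0.06). Among 43 ion channels and neurotransmitter receptors, 24 rose, 5 fell and 14 did not pass (24 and 6 adjusted over the list alone), at adjusted p = 0.001 for the list and adjusted p = 0.105 with an estimated correlation. SCN3A and KCNA1, a sodium and a potassium channel, rose by 3.55 ± 0.12 and 3.10 ± 0.27, while KCNQ3, a potassium channel subunit, fell from 269.7 ± 12.3 to 56.6 ± 4.61. Exons of other genes held 9.9% of SCN3A's exon bases. In full, the neuronal, REST target and channel lists held 51, 34 and 74 members, and those below the filter were not tested. A gene near 0 in the controls could pass the filter only if a vector group raised it, which favours rises in these counts.

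Mitosis genes fell in the libraries labelled Myt1 by small steps. Of 43, 0 rose, 34 fell and 9 did not pass (0 and 36 adjusted over the list alone), at adjusted p = 5.1e-10 for the list and adjusted p = 0.083 with an estimated correlation. CCNB1, the mitotic cyclin, went from 9034 ± 88.5 to 6796 ± 166 (-0.41 ± 0.04, adjusted p = 1.9e-06), and its kinase CDK1 fell by 0.55 on the log2 scale (adjusted p = 3.8e-06). Replication-dependent histones, whose near-identical copies leave read assignment uncertain, fell too, with HIST1H2BK at -1.18 ± 0.09. Most mRNA of these genes lacks a poly-A tail, so poly-A-selected libraries do not measure its level. Of 17 histone genes, 0 rose, 9 fell and 8 did not pass (0 and 10 adjusted over the list alone), at adjusted p = 3.3e-04 for the list and adjusted p = 0.395 with an estimated correlation. Ribosomal protein genes, which have many pseudogene copies, had a median of -0.21. Of 66, 0 rose, 31 fell and 35 did not pass (0 and 31 adjusted over the list alone), at adjusted p = 2.6e-05 for the list and adjusted p = 0.723 with an estimated correlation. RPL4 was at -0.35 ± 0.05 (adjusted p = 4.7e-05).

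Genes driven by YAP and TAZ, the effectors of the Hippo pathway, fell. Of 22 listed targets, 1 rose, 13 fell and 8 did not pass (1 and 13 adjusted over the list alone), at adjusted p = 2.5e-05 for the list and adjusted p = 0.192 with an estimated correlation. AJUBA, a LIM-domain adaptor at cell junctions, dropped from 622 ± 11.9 to 79.8 ± 5.79, or 7.72-fold (-2.95 ± 0.09, adjusted p = 4.0e-12), and CYR61, a matricellular protein, from 823 ± 23.7 to 258 ± 14.5. Neural progenitor and astroglial genes fell as a list. Of 24, 3 rose, 16 fell and 5 did not pass (3 and 16 adjusted over the list alone), at adjusted p = 2.3e-04 for the list and adjusted p = 0.227 with an estimated correlation. GJA1 was among them, with HMGA2, a chromatin protein of embryonic cells (-1.37 ± 0.05), whereas NES, the intermediate filament nestin, rose from 739 ± 48.2 to 1564 ± 39.1 (1.08 ± 0.06, adjusted p = 2.0e-09). Collagens and matrix genes split. Of 62, 19 rose, 32 fell and 11 did not pass (19 and 32 adjusted over the list alone), at adjusted p = 0.002 for the list and adjusted p = 0.340 with an estimated correlation. COL1A2 fell by 1.26 on the log2 scale (adjusted p = 1.4e-11) and FN1, the matrix glycoprotein fibronectin, from 96084 ± 2935 to 42119 ± 2574. FN1 and TGFBR2, a TGF-beta receptor (-1.65 ± 0.05, adjusted p = 4.0e-12), also stood on the list of epithelial-mesenchymal transition regulators. Of 19 on it, 2 rose, 11 fell and 6 did not pass (2 and 12 adjusted over the list alone), at adjusted p = 3.5e-04 for the list and adjusted p = 0.083 with an estimated correlation.

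Smaller list calls completed this comparison. Among mesenchymal glioblastoma genes, 8 rose, 17 fell and 10 did not pass (10 and 18 adjusted over the list alone), at adjusted p = 0.028 for the list and adjusted p = 0.633 with an estimated correlation. ANXA1, a lipid-binding mediator that limits inflammation, fell from 35617 ± 1487 to 11575 ± 611. The mesenchymal call was lost with a filter of 1 CPM (adjusted p = 0.056, in a range of 3.6e-04 to 0.633 over all alternatives). Among hypoxia and glycolysis genes, 7 rose, 19 fell and 8 did not pass (7 and 19 adjusted over the list alone), at adjusted p = 0.031 for the list and adjusted p = 0.486 with an estimated correlation. CA12, a cell surface carbonic anhydrase, fell by 0.87 on the log2 scale. Of 17 heat shock genes, 11 rose, 1 fell and 5 did not pass (12 and 1 adjusted over the list alone), at adjusted p = 1.6e-04 for the list and adjusted p = 0.232 with an estimated correlation. HSPA6, a stress-inducible chaperone whose reads are uncertain because of a near-identical copy, rose from 53.9 ± 0.951 to 456 ± 153, and DNAJB1, a co-chaperone, by 0.57 ± 0.05. Of the BMP and TGF-beta immediate targets, 8 rose, 2 fell and 8 did not pass (8 and 2 adjusted over the list alone), at adjusted p = 0.035 for the list and adjusted p = 0.440 with an estimated correlation. MSX2, a homeobox gene, rose from 9.72 ± 1.14 to 199 ± 10.2. That list's call was lost when the GC and length trend of each library was removed (adjusted p = 0.285, in a range of 1.4e-04 to 0.440 over all alternatives). Without replicate 2 of the libraries labelled Myt1, the BMP and hypoxia calls were lost as well (adjusted p = 0.051 and 0.073, the latter in a range of 3.6e-04 to 0.486 over all alternatives).

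The inflammatory list was not called in this comparison with limma's camera test on the deposited values, though it was called lower with fry (0.008), with edgeR (0.035) and without replicate 1 of the controls (0.046). Its members went far in both directions. Of 43, 11 rose, 18 fell and 14 did not pass (12 and 18 adjusted over the list alone), at adjusted p = 0.139 for the list. IL1B, the cytokine interleukin 1 beta, rose from 2626 ± 134 to 7691 ± 291 (1.55 ± 0.05, adjusted p = 1.5e-11), while CSF3, the growth factor of neutrophils, fell from 2869 ± 296 to 1152 ± 108 (-1.31 ± 0.09, adjusted p = 1.7e-08). In all, 14 of 39 tested lists were called, 5 of them higher and 9 lower. Groups did not overlap for 56.2% of the genes tested, where chance gives 10% for 3 libraries against 3. GC content and transcript length accounted for 7.9% of the variance of log2 fold changes.

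In the libraries labelled Myt1l, neuronal genes also rose and mitosis genes fell, and inflammatory genes fell with them, though the inflammatory list lost its call with an estimated correlation (adjusted p = 0.233). GAP43 rose to 1482 ± 131 normalised reads (3.25 ± 0.08, adjusted p = 5.7e-13), and SCG2, a granin of secretory vesicles in neurons, went from 40.8 ± 4.56 to 468 ± 22.1 (3.49 ± 0.11, adjusted p = 5.3e-12). CSF3 (chromosome 17, 40015361 to 40017813) fell from 2869 ± 296 to 216 ± 15.8, or 13.23-fold (-3.73 ± 0.09, adjusted p = 5.5e-13), and IL1B from 2626 ± 134 to 686, 719 and 746 in the 3 libraries (-1.87 ± 0.05, adjusted p = 3.0e-12). Against control, 4269 genes were higher and 3883 lower, and 763 and 470 of these differed by at least 2-fold. The larger side turned with upper-quartile scaling, to 3798 higher and 4451 lower, with TMM factors from all genes, to 4036 and 4117, and with the GC and length trend removed, to 3622 and 4087. EdgeR, with TMM factors from its filtered genes, gave 4439 higher and 3777 lower.

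NTS again rose most among the named genes, to 402 ± 56.1 (6.12 ± 0.15, adjusted p = 6.9e-13). UNC5C, a netrin receptor, rose from 8.95 ± 3.71 to 191 ± 5.22 (4.34 ± 0.24, adjusted p = 3.5e-09), and ERMN, a cytoskeletal protein of oligodendrocytes, by 4.34 ± 0.22 (adjusted p = 3.1e-09). SCN3A rose by 4.04 ± 0.12 and ISLR2, a membrane protein of axon growth, by 4.04 ± 0.15. MSX2 and NOS1 rose by 3.89 ± 0.14 and 3.87 ± 0.13. THBS1, the matricellular protein thrombospondin, rose from 1201 ± 40.1 to 7235 ± 421, with 7.6% of its exon bases in other genes. NFATC4 fell again (-4.98 ± 0.29, adjusted p = 5.3e-09), and CXCL5, a neutrophil-attracting chemokine, went from 191 ± 16.1 to 19.2 ± 6.75 (-3.29 ± 0.19, adjusted p = 5.8e-09). FGFRL1, a decoy receptor for fibroblast growth factors, fell from 1174 ± 41.6 to 117 ± 19.5, and ABI3BP, a matrix protein, by 3.01 on the log2 scale (adjusted p = 1.9e-12). GJA1 fell to 1831 ± 97.4 (-1.78 ± 0.07).

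Inflammatory cytokines and NF-kappaB targets fell as a list in the libraries labelled Myt1l. Of 43, 7 rose, 32 fell and 4 did not pass (7 and 32 adjusted over the list alone), at adjusted p = 1.1e-08 for the list and adjusted p = 0.233 with an estimated correlation. C3, the central complement component, fell from 15959 ± 689.8 to 4293 ± 24.7 (-1.89 ± 0.05, adjusted p = 6.2e-13). SOD2, the mitochondrial superoxide dismutase that NF-kappaB induces, fell from 9956 ± 393 to 4120 ± 90.9. LIF, a cytokine of the IL6 family, fell by 1.88 on the log2 scale. IL7R, a cytokine receptor, was higher than control (0.23 ± 0.06). Among mesenchymal glioblastoma genes, 9 rose, 18 fell and 8 did not pass (9 and 18 adjusted over the list alone), at adjusted p = 0.032 for the list and adjusted p = 0.428 with an estimated correlation. The mesenchymal call was lost without replicate 2 of the controls (adjusted p = 0.061), and without replicate 1 or replicate 2 of the libraries labelled Myt1l (0.058 for each). No variance trend gave 0.053, and the range was 5.7e-04 to 0.428 over all alternatives.

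The neuronal list rose in the libraries labelled Myt1l as well, and it held with an estimated correlation. Of its members, 24 rose, 4 fell and 6 did not pass (27 and 4 adjusted over the list alone), at adjusted p = 4.3e-09 for the list and adjusted p = 0.032 with an estimated correlation. RTN1, a reticulon of neuroendocrine cells, rose from 728 ± 10.5 to 2257 ± 84.3 (1.63 ± 0.05, adjusted p = 4.0e-12). Among REST targets, 15 rose, 2 fell and 4 did not pass (16 and 2 adjusted over the list alone), at adjusted p = 7.2e-06 for the list and adjusted p = 0.188 with an estimated correlation. MAPK8IP2, a scaffold of the JNK pathway in brain, rose by 1.69 ± 0.14. REST fell to 721 ± 58.9 (-0.66 ± 0.07, adjusted p = 3.0e-06). Of the ion channels and receptors, 22 rose, 7 fell and 14 did not pass (23 and 7 adjusted over the list alone), at adjusted p = 0.006 for the list and adjusted p = 0.188 with an estimated correlation. GABRA2, a subunit of the GABA receptor, rose by 2.00 ± 0.11, and SCN9A, a sodium channel with 8.2% of its exon bases in other genes, by 2.53 ± 0.14.

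Cell cycle genes fell with the Myt1l label too. Of 43 mitosis genes, 0 rose, 40 fell and 3 did not pass (0 and 40 adjusted over the list alone), at adjusted p = 5.1e-17 for the list and adjusted p = 0.032 with an estimated correlation, so that the call held with both. TOP2A, the topoisomerase of dividing cells, went from 13742 ± 266 to 8787 ± 522 (-0.65 ± 0.05, adjusted p = 6.0e-08), and ASPM, a spindle pole protein, from 5375 ± 175 to 2707 ± 425. Of 40 DNA replication genes, 6 rose, 19 fell and 15 did not pass (7 and 20 adjusted over the list alone), at adjusted p = 0.003 for the list and adjusted p = 0.233 with an estimated correlation. Examples were RRM1, the large subunit of ribonucleotide reductase (-0.49 ± 0.04), and POLA1, the catalytic subunit of the priming polymerase (-0.55 ± 0.05). Of the histone genes, 0 rose, 10 fell and 7 did not pass (0 and 10 adjusted over the list alone), at adjusted p = 8.3e-04 for the list and adjusted p = 0.287 with an estimated correlation. Poly-A selection limits the reading of histone genes here as well. Of the ribosomal protein genes, 2 rose, 16 fell and 48 did not pass (0 and 8 adjusted over the list alone), at adjusted p = 0.024 for the list and adjusted p = 0.722 with an estimated correlation. The ribosomal call was lost without replicate 1 or replicate 2 of the libraries labelled Myt1l (adjusted p = 0.163 and 0.215), with edgeR (0.092) and with fry (0.171), in a range of 2.0e-05 to 0.722 over all alternatives.

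Stress response genes rose in the libraries labelled Myt1l. Of 44 genes of the unfolded protein and integrated stress response, 28 rose, 6 fell and 10 did not pass (30 and 8 adjusted over the list alone), at adjusted p = 2.2e-04 for the list and adjusted p = 0.233 with an estimated correlation. HSPA5, the chief chaperone of the endoplasmic reticulum, went from 20783 ± 117 to 32746 ± 635 (0.66 ± 0.04, adjusted p = 6.0e-09), and NUPR1, a small stress-induced nuclear protein, rose by 1.22 ± 0.06. Among heat shock genes, 14 rose, 0 fell and 3 did not pass (14 and 0 adjusted over the list alone), at adjusted p = 1.9e-06 for the list and adjusted p = 0.188 with an estimated correlation. DNAJB1 rose from 5493 ± 125 to 10530 ± 528 and BAG3, a co-chaperone of selective autophagy, by 0.80 ± 0.06. Of 33 p53 targets, 15 rose, 3 fell and 15 did not pass (19 and 3 adjusted over the list alone), at adjusted p = 0.013 for the list and adjusted p = 0.255 with an estimated correlation. TP53I3, an oxidoreductase gene, rose by 0.88 ± 0.09. Among BMP and TGF-beta targets, 9 rose, 0 fell and 9 did not pass (9 and 0 adjusted over the list alone), at adjusted p = 0.005 for the list and adjusted p = 0.233 with an estimated correlation. ID3, an inhibitor of helix-loop-helix factors, rose by 0.68 ± 0.08 and PMEPA1, a feedback inhibitor of TGF-beta signalling, by 1.11 ± 0.06. With the GC and length trend removed, the p53 list lost its call and its median went from 0.19 to 0.09 (adjusted p = 0.088, in a range of 2.5e-04 to 0.255 over all alternatives). The BMP list lost its call too, while its median went from 0.24 to 0.20 (adjusted p = 0.059, in a range of 3.5e-05 to 0.233 over all alternatives). Nuclear-encoded respiratory chain genes had a median of 0.16, with NDUFB10 at 0.39 ± 0.07. Of 50, 22 rose, 0 fell and 28 did not pass (21 and 0 adjusted over the list alone), at adjusted p = 0.003 for the list and adjusted p = 0.658 with an estimated correlation. The respiratory call was lost with fry (0.059), in a range of 8.2e-06 to 0.658 over all alternatives.

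YAP and TAZ targets, progenitor genes and transition regulators fell, and adhesion genes rose. Of the YAP and TAZ targets, 3 rose, 13 fell and 6 did not pass (3 and 14 adjusted over the list alone), at adjusted p = 4.8e-04 for the list and adjusted p = 0.233 with an estimated correlation. AJUBA fell to 152 ± 3.57 (-2.02 ± 0.09, adjusted p = 2.4e-10). For progenitor and astroglial genes, 3 rose, 13 fell and 8 did not pass (3 and 13 adjusted over the list alone), at adjusted p = 0.005 for the list and adjusted p = 0.255 with an estimated correlation. NES rose by 0.98 ± 0.06. Among transition regulators, 4 rose, 11 fell and 4 did not pass (4 and 12 adjusted over the list alone), at adjusted p = 0.013 for the list and adjusted p = 0.188 with an estimated correlation. PRRX1, a mesenchymal homeobox gene, was at -0.92 ± 0.05. Of 36 integrins, cadherins and other adhesion genes, 20 rose, 7 fell and 9 did not pass (22 and 7 adjusted over the list alone), at adjusted p = 0.003 for the list and adjusted p = 0.233 with an estimated correlation. PCDH10, a protocadherin of neurons, rose from 85.0 ± 6.06 to 385 ± 22.4 (2.17 ± 0.09, adjusted p = 2.0e-10), and CDH7, a cadherin of neural crest, by 1.51 ± 0.10. In all, 18 of 39 lists were called, 9 higher and 9 lower. Groups did not overlap for 57.2% of genes, and GC content and length accounted for 11.5% of the variance of log2 fold changes.

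**Figure D2:**
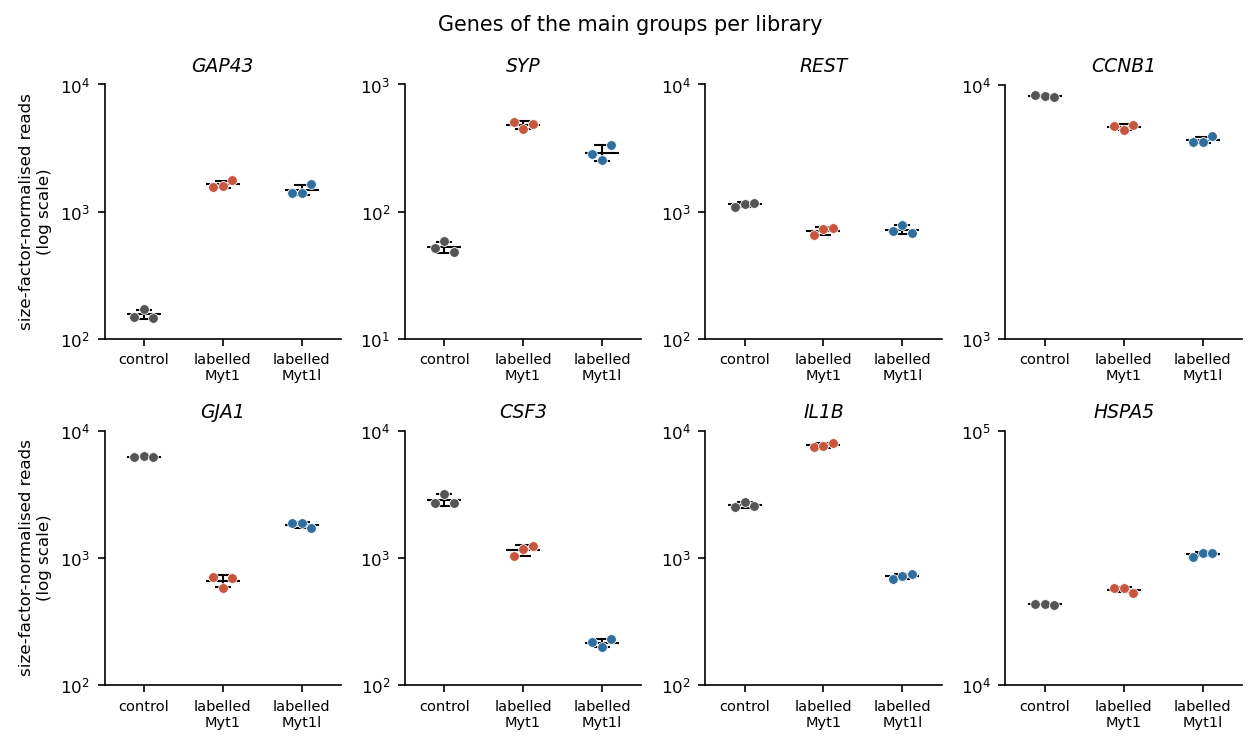
Normalised reads of 8 genes named in the text (log axis), with points for libraries and bars for the mean ± SD of the 3 libraries of a group. GAP43 was near 155 in the controls and above 1000 in both other groups, and IL1B was higher than control in the libraries labelled Myt1 and lower in those labelled Myt1l.

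Many genes moved in a common direction in both vector groups. Of the genes called against control, 2846 were higher in both comparisons, 2483 lower in both and 138 went opposite ways. Here too the larger side turned, to 2667 and 2705 with upper-quartile scaling, 2586 and 2755 with TMM factors and 2357 and 2938 with the GC and length trend removed. Lists that were independent of each other would share 915 and 792 in a common direction. Log2 fold changes correlated across genes, which are not independent replicates, at Pearson's r = 0.77 and Spearman's rho = 0.75. Both comparisons use the same 3 controls. In 100 draws every library, controls included, was simulated without change, which gave 0.43 to 0.53 and 0.41 to 0.45. Differences in GC content between the real libraries were not part of the draws. The covariance of log2 fold changes was 0.3109, against 0.0240 to 0.0320 in the draws. How many calls unrelated changes would share through the controls was not tested, so part of the shared calls may come from them. With 3 controls, no split leaves 2 libraries in each part. NTS, GAP43, RCAN2, DRAXIN, SYP, SCN3A and MSX2 rose in both groups, while NFATC4, IFI44L, GJA1, FGFRL1, AJUBA and CSF3 fell in both. NRG1, the growth factor neuregulin, fell from 1886 ± 71.1 to 485 ± 6.24 and 561 ± 57.6.

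**Figure D3:**
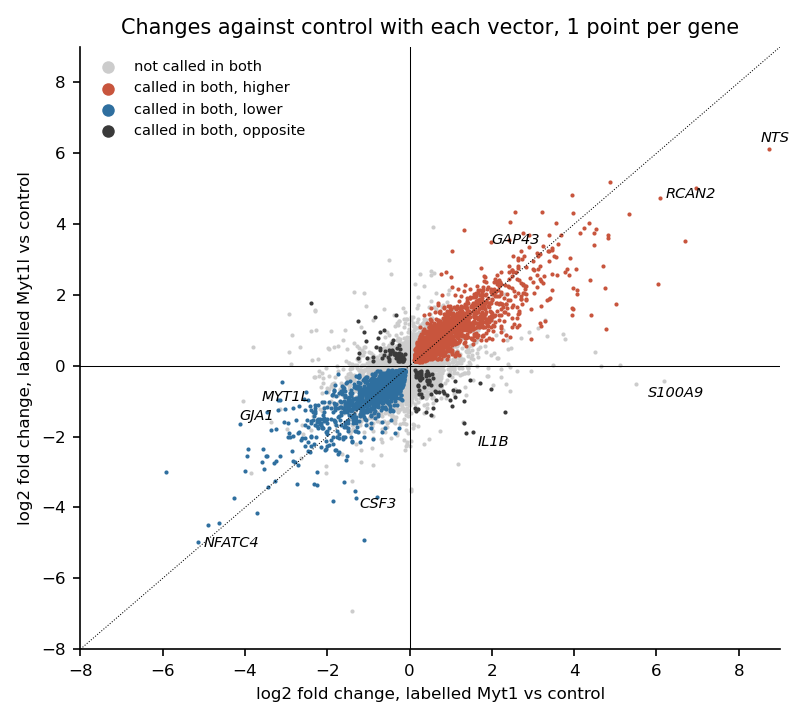
Each point is a gene, placed by its log2 fold change against control in the libraries labelled Myt1 (horizontal) and labelled Myt1l (vertical), with the dotted line marking equal changes. Red marks the 2846 genes higher in both, blue the 2483 lower in both, dark the 138 called in opposite directions, and grey all others.

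Set against each other, the libraries labelled Myt1l held less inflammatory and cell cycle mRNA than those labelled Myt1 and more matrix and stress response mRNA. None of these list calls held with an estimated correlation (adjusted p = 0.128 for mitosis and 0.162 each for inflammation, DNA replication, matrix and the unfolded protein response). IL1B (chromosome 2, 112829751 to 112836903) stood at 7419, 7657 and 7997 normalised reads with the Myt1 label and at 686, 719 and 746 with the Myt1l label, 10.71-fold lower (-3.42 ± 0.05, adjusted p = 8.0e-15), having moved opposite ways against control. THBS1 stood at 2031 ± 67.3 and 7235 ± 421 (1.83 ± 0.05, adjusted p = 1.4e-11). This comparison tests the difference between the vector groups itself, and 1956 genes were higher and 1621 lower with the Myt1l label. With upper-quartile scaling the split turned to 1558 higher and 1999 lower, so the larger side depended on the scaling.

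Among the named genes, S100A9 differed most. It stood at 314 ± 45.5 with the Myt1 label against 2.46 ± 1.71 (-6.62 ± 0.39, adjusted p = 2.5e-08), and SOST, ADAMTS9, a matrix protease, and PTGS1 had log2 fold changes of -3.73 ± 0.22, -3.64 ± 0.16 and -3.16 ± 0.21. Higher with the Myt1l label were IGFBP1, a carrier of insulin-like growth factors (2.63 ± 0.12, adjusted p = 1.5e-09), and PDK4, a kinase that restrains pyruvate use (2.34 ± 0.18, adjusted p = 3.1e-07). DEPTOR, an mTOR inhibitor, and EPHA3, an ephrin receptor, were higher too (2.22 ± 0.15 and 2.20 ± 0.17).

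Of 43 inflammatory genes, 5 were higher, 26 lower and 12 not called (5 and 28 adjusted over the list alone), at adjusted p = 1.7e-11 for the list and adjusted p = 0.162 with an estimated correlation. CSF3, C3 and SOD2 had log2 fold changes of -2.41 ± 0.09, -1.54 ± 0.05 and -1.44 ± 0.05, and IL7R was higher (1.49 ± 0.06). Of the mitosis genes, 0 were higher, 26 lower and 17 not called (0 and 30 adjusted over the list alone), at adjusted p = 6.4e-13 for the list and adjusted p = 0.128 with an estimated correlation. Of the DNA replication genes, 0 were higher, 15 lower and 25 not called (0 and 16 adjusted over the list alone), at adjusted p = 2.4e-06 for the list and adjusted p = 0.162 with an estimated correlation. ASPM was at -0.64 ± 0.09 and KIF20B, a kinesin of cytokinesis, at -0.34 ± 0.05. Among collagens and matrix genes, 28 were higher, 8 lower and 26 not called (31 and 11 adjusted over the list alone), at adjusted p = 3.0e-05 for the list and adjusted p = 0.162 with an estimated correlation. COL13A1, a transmembrane collagen, stood at 110.2 ± 7.68 and 343 ± 32.9 (1.63 ± 0.09, adjusted p = 1.8e-08). Among adhesion genes, 14 were higher, 3 lower and 19 not called (17 and 6 adjusted over the list alone), at adjusted p = 3.1e-04 for the list and adjusted p = 0.199 with an estimated correlation. CDH7 was at 1.62 ± 0.10. Among YAP and TAZ targets, 9 were higher, 2 lower and 11 not called (9 and 2 adjusted over the list alone), at adjusted p = 0.013 for the list and adjusted p = 0.412 with an estimated correlation. Among transition regulators, 9 were higher, 4 lower and 6 not called (9 and 4 adjusted over the list alone), at adjusted p = 0.028 for the list and adjusted p = 0.162 with an estimated correlation. CYR61 of the former was at 0.96 ± 0.07 and TGFBR2 of the latter at 1.08 ± 0.05. These last lists lost their call without replicate 2 of the libraries labelled Myt1l (adjusted p = 0.066 for each, in ranges of 1.6e-04 to 0.412 over all alternatives and 9.6e-05 to 0.162 over all alternatives).

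Stress lists were higher with the Myt1l label. For the unfolded protein and integrated stress response, 27 were higher, 5 lower and 12 not called (28 and 6 adjusted over the list alone), at adjusted p = 2.5e-07 for the list and adjusted p = 0.162 with an estimated correlation. SLC7A11, the cystine transporter, stood at 867 ± 53.9 and 2976 ± 428 (1.77 ± 0.09, adjusted p = 2.6e-08). For p53 targets, 12 were higher, 0 lower and 21 not called (13 and 0 adjusted over the list alone), at adjusted p = 2.2e-05 for the list and adjusted p = 0.162 with an estimated correlation. PMAIP1, which encodes the pro-apoptotic protein NOXA, was at 0.59 ± 0.07. For heat shock genes, 9 were higher, 0 lower and 8 not called (9 and 1 adjusted over the list alone), at adjusted p = 0.004 for the list and adjusted p = 0.355 with an estimated correlation. DNAJB4, a co-chaperone, was at 0.81 ± 0.09. The heat shock call was lost without replicate 3 of the libraries labelled Myt1 (adjusted p = 0.053, in a range of 1.8e-05 to 0.355 over all alternatives). For respiratory chain genes, with a median of 0.14, 12 were higher, 0 lower and 38 not called (13 and 0 adjusted over the list alone), at adjusted p = 1.8e-04 for the list and adjusted p = 0.639 with an estimated correlation. The respiratory call was lost with fry (0.103), in a range of 4.7e-08 to 0.639 over all alternatives. For ribosomal protein genes, 4 were higher, 0 lower and 62 not called (0 and 0 adjusted over the list alone), at adjusted p = 0.015 for the list and adjusted p = 0.774 with an estimated correlation. The ribosomal call was lost without replicate 3 of the libraries labelled Myt1l (adjusted p = 0.862), without replicate 2 of those labelled Myt1 (0.060), with edgeR (0.058), with fry (0.292) and with the GC trend removed (0.059), in a range of 1.2e-04 to 0.862 over all alternatives. The chromatin regulators known to work with this factor family were called lower. Of 32, 1 were higher, 5 lower and 26 not called (0 and 5 adjusted over the list alone), at adjusted p = 0.043 for the list and adjusted p = 0.201 with an estimated correlation. Beside a main median of -0.08, that call was lost with edgeR (0.094, median -0.09) and TMM factors (0.060, median -0.07). The call was also lost with the GC trend removed (0.070, median -0.07) or no variance trend (0.062, median -0.08). It was lost too without replicate 2 of the controls (0.052), replicate 3 of the libraries labelled Myt1 (0.078) or replicate 2 of those labelled Myt1l (0.066), in a range of 0.003 to 0.201 over all alternatives.

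With camera on the deposited values, neuronal lists were not called between the vector groups. Of the neuronal genes, 7 were higher, 11 lower and 16 not called (7 and 11 adjusted over the list alone), at adjusted p = 0.235 for the list. Of the REST targets, 2 were higher, 8 lower and 11 not called (2 and 8 adjusted over the list alone), at adjusted p = 0.053 for the list. The REST list lay at the threshold and was called lower in 12 of 24 alternatives, among them edgeR (0.027), fry (0.016) and the removal of the GC and length trend (0.032). The neuronal list was called lower with fry alone (0.009). Within them DCLK1 and VGF were lower with the Myt1l label (-1.62 ± 0.08 and -1.53 ± 0.14), SCG2 was higher (1.51 ± 0.11), and GAP43 was at -0.15 ± 0.08 (adjusted p = 0.209). In all, 13 of 39 lists were called, 9 higher and 4 lower, and none held with an estimated correlation. Groups did not overlap for 36.7% of genes, and GC content and length accounted for 1.5% of the variance.

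**Figure D4:**
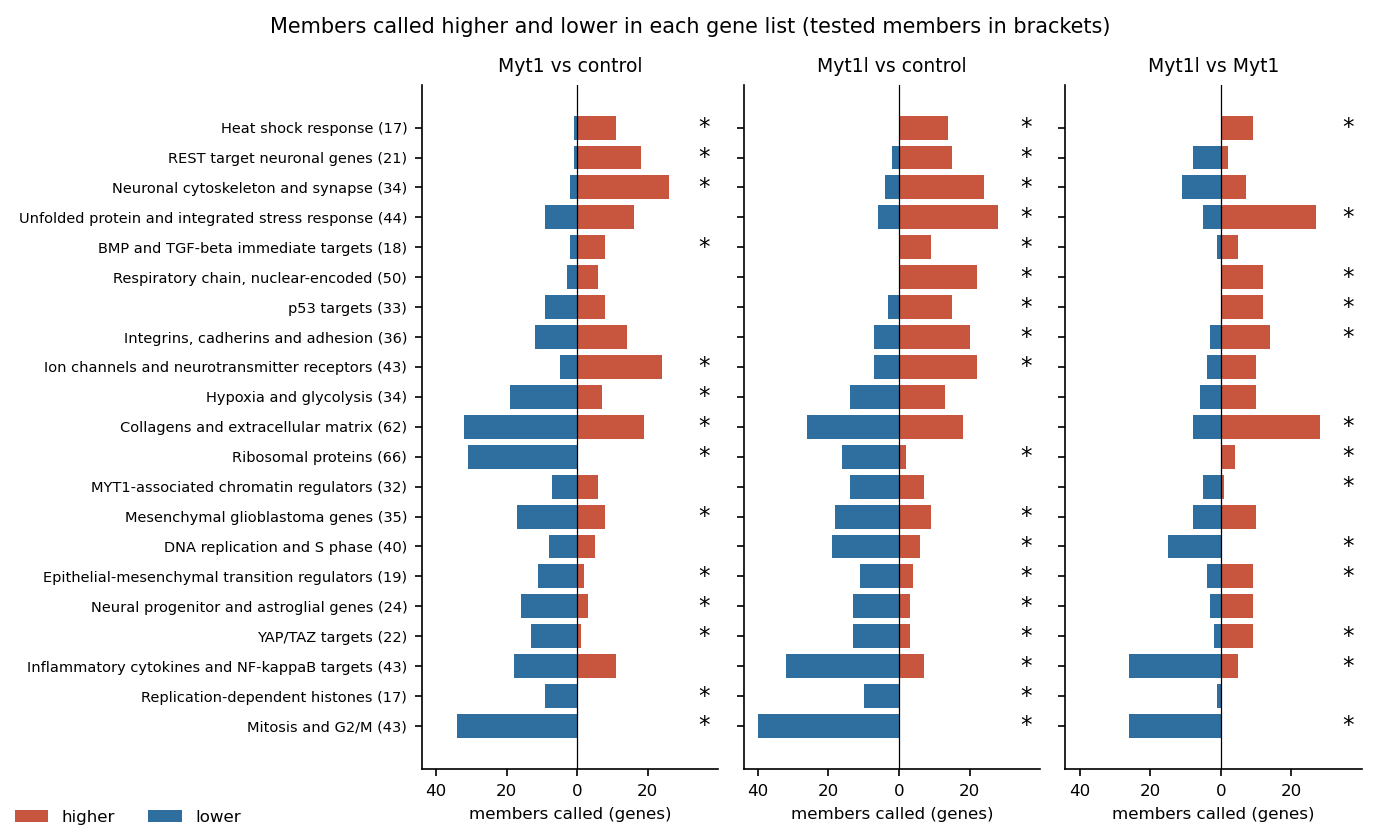
Number of members of each gene list called higher (bars to the right) and lower (bars to the left) in the 3 comparisons, for the lists called in at least 1 of them, with the tested members in brackets and an asterisk where the list was called. Mitosis genes were lower for 34, 40 and 26 of 43 tested members, and none was higher.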

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

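The TMM factors, edgeR on recovered reads, the pseudocounts, the model without a variance trend and the removal of the GC and length trend were tests chosen after the results were seen. EdgeR itself had been planned as the main test, on deposited counts. On recovered reads it called 7229, 8216 and 3581 genes for Myt1 vs control, Myt1l vs control and Myt1l vs Myt1. Of these, limma called 6922, 7996 and 3479 in the same direction. Over all alternatives, called named genes kept their direction and their call in 17870 cases, kept only the direction in 845 and reversed in 12, and named genes not called reversed in 9. Called lists kept both in 1007 cases, kept only the direction in 73 and reversed in 0. These cases count the same 721 gene calls and 45 list calls again in each alternative. The test for at least 1.5-fold alone ended 406 of the gene calls, and an estimated correlation ended 42 of the list calls. Most named genes were chosen for large changes or small adjusted p, so their cases do not stand for all calls. Over the 14826 genes with GC content, removal of the GC and length trend kept 4847 of 6766 calls in direction for Myt1 vs control. Another 112 were called the opposite way. These counts were 5484 of 7684 and 205 for Myt1l vs control, and 3294 of 3397 and 0 for Myt1l vs Myt1. A test for a fold change of at least 1.5 asks more of each gene and called 1087, 1015 and 209 genes for Myt1 vs control, Myt1l vs control and Myt1l vs Myt1. It called 650 genes in both comparisons with control, and MYT1L at -1.25 in the libraries labelled Myt1l was not called (adjusted p = 0.071). At an adjusted p under 0.01, 1897 genes differed between the vector groups. An estimated correlation called 1, 2 and 0 lists, while fry, which compares no list with other genes, called 28, 30 and 24.

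Leaving out each library in turn gave 5905 to 8404, 6966 to 8086 and 2439 to 3688 genes and 12 to 15, 16 to 19 and 10 to 14 lists. MYT1L against control in the libraries labelled Myt1l ranged from -1.43 to -0.98, shared calls from 4377 to 5990 and the correlation of fold changes from 0.73 to 0.78. Replicate numbers as a replicate block gave 7114, 8132 and 3545 genes, but the numbers carry no stated pairing: deviations of libraries with the same number correlated at -0.20 to 0.06 over 9 pairs, and 0 matched best by number. Without replicate 3 of the libraries labelled Myt1l, which stood apart, 8404, 7990 and 3688 genes were called. TMM factors from all genes turned the split for Myt1 vs control to 3282 higher and 3878 lower. With TMM factors from filtered genes, edgeR gave 3940 higher and 3289 lower.

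The named genes that reversed did so with the GC content and length trend removed, and whether that trend is technical was not tested. For Myt1 vs control these were NDUFV1 (-0.02), NLRC5 (-0.11), CHAC1 (-0.05), TGFBR1 (0.11), SIN3B (-0.07), HCN2 (-0.49), COX6C (0.16), ATP5C1 (0.04), MYH9 (-0.28), CHD4 (-0.01), SUZ12 (0.10), REEP5 (0.13) and EMC7 (0.10). For Myt1l vs control they included CDT1 (-0.04), NDUFV1 (-0.01), POLR2A (-0.05), NOTCH3 (-0.37), TCF7 (-0.12), HCN2 (-0.11) and PCDH9 (0.05). Other causes were not tested. Median-of-ratios scaling is the deposited scale itself and gave no separate value, and the motif alternatives were not run. At 15598124 to 29928017 reads per library, 1.5-fold changes were found in 64.2% to 73.1% of simulated genes, which left out genes with few reads in the controls. Far fewer genes were changed there than were called in the real data. No GC trend was simulated either, so these rates may not carry over. MYT1 was listed at 0 in each library, and nothing was read from that 0.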

Other observations

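The tests of a mislabelled library, of exchanged groups and of a copy number change below, the neighbours of IL1B, edgeR on recovered reads and the removal of the GC and length trend were chosen after the results were seen. The plan had named edgeR on deposited counts as the main test. With camera on the deposited values, several gene groups were called in no comparison, though some of their members were called. Of all genes tested, 41.8% were called in Myt1 vs control and 47.7% in Myt1l vs control. A count of members near these shares is therefore no trait of a list. Fry, which compares no list with other genes, called 41 lists that camera did not over the 3 comparisons, and calls that other alternatives gave to the lists of this part are named below. Counts are members that rose and fell against control, with those adjusted over the list alone and the adjusted p of the list in brackets. Of 17 Notch pathway genes, 8 and 6 (8 and 7 alone, adjusted p = 0.641) changed in the libraries labelled Myt1 and 10 and 5 (10 and 5 alone, adjusted p = 0.220) in those labelled Myt1l. NOTCH1, the receptor, fell from 964 ± 61.5 to 487 ± 40.6 and 449 ± 32.3 normalised reads, while HES1, a target of the pathway, rose in the libraries labelled Myt1l (1.10 ± 0.15, adjusted p = 3.6e-05). For 17 Wnt targets the counts were 5 and 9 (5 and 9 alone, adjusted p = 0.401) and 6 and 4 (6 and 4 alone, adjusted p = 0.595), and in the libraries labelled Myt1 the list's median of -0.18 and mean of 0.07 differed in sign. LGR5, an R-spondin receptor, rose in the libraries labelled Myt1 (4.69 ± 0.35, adjusted p = 7.3e-08), and DKK1, a secreted Wnt inhibitor, differed between the vector groups by 1.57 ± 0.09 (adjusted p = 2.1e-08). Proneural and neuronal transcription factors gave 4 and 2 (4 and 2 alone, adjusted p = 0.719) and 3 and 5 (4 and 5 alone, adjusted p = 0.584) of 14, with BCL11B at 0.56 ± 0.14 and -1.18 ± 0.14, opposite ways in the 2 vector groups. Their median in the libraries labelled Myt1l was 0.03 where the test pointed lower. Axon guidance genes gave 18 and 15 (18 and 15 alone, adjusted p = 0.641) and 23 and 11 (23 and 11 alone, adjusted p = 0.104) of 51. PLXNA2, a semaphorin receptor, rose from 1158 ± 38.8 to 5268 ± 271 and 2841 ± 191, whereas EPHA2, an ephrin receptor, fell in the libraries labelled Myt1 (-1.73 ± 0.06, adjusted p = 1.1e-11). Growth factors and their receptors gave 18 and 22 (19 and 24 alone, adjusted p = 0.590) and 23 and 20 (24 and 20 alone, adjusted p = 0.961) of 57, with a median of -0.07 and a mean of 0.13 in the libraries labelled Myt1. Interferon-stimulated genes gave 9 and 14 (9 and 14 alone, adjusted p = 0.502) and 7 and 13 (8 and 14 alone, adjusted p = 0.209) of 36: OAS2, an antiviral enzyme, was at -2.79 ± 0.23 and -2.71 ± 0.23, and ISG15, a ubiquitin-like modifier, at 0.85 ± 0.11 and 1.16 ± 0.11. Antigen presentation gave 3 and 3 (3 and 3 alone, adjusted p = 0.641) and 1 and 5 (1 and 5 alone, adjusted p = 0.244) of 11, and immediate early genes 8 and 14 (8 and 15 alone, adjusted p = 0.362) and 6 and 15 (6 and 15 alone, adjusted p = 0.148) of 35, with EGR2, an early growth response factor, at 1.02 ± 0.07 and 1.41 ± 0.07. With the GC and length trend removed, the immediate early list was called lower in both comparisons (median -0.34, adjusted p = 0.004, and median -0.23, adjusted p = 4.0e-04), and without replicate 3 of the libraries labelled Myt1l in the second (0.046). With no filter beyond 1 read, the Notch and axon guidance lists were called higher in the libraries labelled Myt1l (0.019 each). With the GC and length trend removed, neither was called and their medians there went from 0.47 to 0.05 and from 0.14 to 0.09 (adjusted p = 0.646 and 0.378). Between the vector groups, Wnt targets were called higher with no filter beyond 1 read (0.045), axon guidance higher with edgeR (0.045), and proneural factors lower with a filter of 1 CPM (0.014) and with a replicate block (0.049). Between them, neural progenitor genes were called higher with edgeR (0.007), without replicate 3 of the libraries labelled Myt1l (0.033) and without replicate 1 of those labelled Myt1 (0.049), and hypoxia genes higher with no filter beyond 1 read (0.010).

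Markers of other cell types gave no list called by camera on the deposited values, but smooth muscle genes were called lower in the libraries labelled Myt1 with the GC and length trend removed (median -0.28, adjusted p = 0.001). Oligodendrocyte genes gave 4 and 3 (4 and 4 alone, adjusted p = 0.802) and 2 and 1 (2 and 1 alone, adjusted p = 0.825) of 12, melanocyte and neural crest genes 3 and 6 (5 and 7 alone, adjusted p = 0.719) and 4 and 4 (4 and 5 alone, adjusted p = 0.961) of 15, and macrophage and microglia markers 3 and 2 (3 and 2 alone, adjusted p = 0.641) and 3 and 2 (4 and 3 alone, adjusted p = 0.913) of 8. MITF, a master factor of melanocytes, fell from 549 ± 6.79 to 159.6 ± 31.4 and 302 ± 21.8. Endothelial markers gave 1 and 1 (1 and 1 alone, adjusted p = 0.641) and 3 and 1 (3 and 1 alone, adjusted p = 0.530) of 7, epithelial markers 5 and 1 (5 and 1 alone, adjusted p = 0.641) and 5 and 1 (6 and 2 alone, adjusted p = 0.266) of 10, smooth muscle genes 3 and 8 (3 and 8 alone, adjusted p = 0.312) and 5 and 9 (6 and 10 alone, adjusted p = 0.691) of 23, and skeletal muscle genes 1 and 1 (1 and 1 alone, adjusted p = 0.724) and 1 and 2 (1 and 2 alone, adjusted p = 0.362) of 6. The melanocyte list had medians of -0.07 and -0.10 beside means of 0.12 and 0.17, and the smooth muscle list -0.09 beside 0.03 in the libraries labelled Myt1l. Cholesterol genes gave 10 and 5 (10 and 5 alone, adjusted p = 0.590) and 10 and 4 (10 and 4 alone, adjusted p = 0.137) of 29, and were called higher in the libraries labelled Myt1l with no filter beyond 1 read (0.015). Matrix proteases gave 13 and 17 (14 and 17 alone, adjusted p = 0.667) and 15 and 15 (15 and 15 alone, adjusted p = 0.691) of 36, with a median of 0.01 and a mean of 0.11 where the test pointed lower in the libraries labelled Myt1, and of 0.02 and -0.02 in those labelled Myt1l. Chromatin regulators gave 6 and 7 (6 and 7 alone, adjusted p = 0.724) and 7 and 14 (7 and 14 alone, adjusted p = 0.137) of 32, and housekeeping genes 4 and 5 (4 and 5 alone, adjusted p = 0.964) and 9 and 5 (9 and 5 alone, adjusted p = 0.530) of 30. In the libraries labelled Myt1, DNA replication gave 5 and 8 (5 and 8 alone, adjusted p = 0.724), p53 targets 8 and 9 (8 and 9 alone, adjusted p = 0.724), the unfolded protein response 16 and 9 (16 and 9 alone, adjusted p = 0.641) and the respiratory chain 6 and 3 (4 and 3 alone, adjusted p = 0.724). Adhesion genes gave 14 and 12 (14 and 12 alone, adjusted p = 0.719), with a median of -0.03 and a mean of 0.31. In those labelled Myt1l, collagens gave 18 and 26 (21 and 26 alone, adjusted p = 0.340) and hypoxia genes 13 and 14 (13 and 14 alone, adjusted p = 0.522). The collagen list was called lower there with the GC and length trend removed (median -0.26, adjusted p = 0.011). None of the 13 mitochondrially encoded mRNAs was tested, as all were listed at 0.

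MYT1 was listed at 0 in every library, and MYT1L was lower in the libraries labelled Myt1l than in the controls. Of the 9 libraries, 0 resembled another group most, which argues against a mislabelled library. Exons of other genes cover 5.0% of MYT1L's exon bases. The share of its reads that came from them was not measured, so this cannot decide whether they shaped its level. Whether the labels of whole groups were exchanged cannot be told apart from vectors whose sequence is not counted at the human genes. MYT1 could not decide it, because it was listed at 0 in all 9 libraries and nothing was read from that 0. A biological effect of the factors on the native MYT1L gene was not tested and stays open too.

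Neuronal and REST target genes rose and mitosis genes fell against control in both vector groups. With an estimated correlation the REST call was lost in both comparisons (adjusted p = 0.105 and 0.188) and the mitosis call in Myt1 vs control (adjusted p = 0.083). A trend with GC content and transcript length may distort such lists, but after its removal the medians of the 3 lists kept at least 0.80 of their size in both comparisons. Shared controls make comparisons resemble each other, and the observed covariance of 0.3109 lay above the highest simulated value of 0.0320. The draws simulated the controls as well, so they do not cover a deviation particular to the real control libraries. An effect of both factors on the same genes stays open as a hypothesis, as does any difference between the control culture and the vector cultures other than the factor.

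All 8 tested genes between 112829751 and 113278950 on chromosome 2 were lower in the libraries labelled Myt1l than in those labelled Myt1. IL1B was at -3.42, IL36RN at -2.28, IL36B at -1.87, IL1RN at -1.71, PAX8 at -0.99 and PSD4 at -0.78 (log2). IL37, which had few reads, was at -3.48 and the non-coding PAX8-AS1 at -2.09. Against control, the libraries labelled Myt1l had -1.87, -2.26, -1.91, -1.30, -0.86 and -0.57 for the first 6 in this order. PAX8-AS1 was at -2.16 there, but IL37 did not fall (0.01, adjusted p = 0.989). In the libraries labelled Myt1, IL37 rose against control (3.49), as did IL1B (1.55) and IL1RN (0.41). A copy number change of the region would move its genes alike. The highest and lowest of the first 6 differed by 18.2 combined standard errors, but IL1B, the lowest, had also risen with the Myt1 label. The 19 tested genes within 1 Mb had a median of -0.17 (-0.80 to 2.24), but the span was chosen after the results were seen. These values therefore cannot decide on a copy number change limited to the span. Overlap with other genes reached 10% of exon bases in 0 of the same 6 (9.3% in PAX8, 0.0% in IL37 and 4.0% in PAX8-AS1). A fall of NF-kappaB targets across the genome stays open as part of the cause. The inflammatory list without chromosome 2 had a median of -0.52 (38 genes, 4 higher, 24 lower, adjusted p = 8.5e-11, and adjusted p = 0.174 with an estimated correlation). Most members of the list lie off chromosome 2, so this largely restates the list's fall and does not link it to these genes.

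With 3 libraries in each group, 10 splits of the 6 libraries compared are possible, so the share of splits with as large a result cannot go under 0.05 (the smallest is 0.1). Genes called were 7142 in the real split and 0 in the highest other for Myt1 vs control, 8152 and 1 for Myt1l vs control, and 3577 and 1 for Myt1l vs Myt1. Lists called were 14 and 13, 18 and 14, and 13 and 10. Every other split mixes the groups, so a real difference enters its spread and few gene calls are to be foreseen. Such a split also keeps part of that difference, so neither count is a baseline free of it.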
